A study of Mus musculus and Homo sapiens with 116 samples.

How the data were processed

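Polyadenylated RNA had been sequenced from mouse BMDM and human mDM 5 h after PBS, LPS (100 ng/mL) or MSU (250 µg/mL), per the labels' protocols. Mouse cells were C57BL/6 bone marrow grown with L929-conditioned medium and then M-CSF. SP600125 (20 µM) or BAY-876 (20 nM) had been added 1 h before the stimulus. Libraries were made with a dUTP method that marks strand, per the labels, but whether strand was used in counting is not given in the sources used here. Reads were aligned with STAR to mm10 or hg38, per the submitters' processing notes, and the file names name HOMER. Versions of STAR and HOMER are not given in the sources used here.

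All 7 tables hold TPM, a length-corrected share of a library's reads, which the authors had scaled per library before 1 transcript per gene was kept, as the deposited values show. Listed values therefore summed to between 361966 and 592782 per library. The tables give no read counts. Because TPM is reads divided by transcript length up to a factor per library, that factor was sought for which low values times length became whole numbers. It was accepted where at least 95% of low values came within 0.1 of a whole number, which held for all but 1 siJun and 1 siFosl1 library. The reads recovered this way are estimates, given only as depth and for 1 alternative. The median SD of log2 values within groups was 0.13 in the inhibitor set, 0.172 in the Myd88 set, 0.19 in the siRNA set, 0.224 in the BMDM set and 0.373 in mDM, over genes with a mean above 5 TPM. File starts of 356 of 511 named mouse genes equalled the 1-based reference start, and 0 lay 1 below it, so coordinates are printed as listed.

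Columns were mapped to samples by condition and replicate number. Labels of 6 libraries disagree with each other, on the organism in 1 mDM library and on the agent or treatment in 5 BMDM libraries (Bay PBS, LPS and MSU replicate 6, siFosl1 LPS and MSU replicate 1). They stayed in the group their title gives, and alternatives left them out. The tables for siControl, siJun and siFosl1 were joined by gene for a single fit, without further scaling.

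Tests used limma 3.58.1 with trend in R 4.3.3 on log2(TPM + 1), with 1 coefficient per group and all groups of a set in the fit. Genes entered with at least 1 TPM in as many libraries as the smallest group of the set has. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and at least a 2-fold change. Interactions were contrasts of the same fit. Written before the data were examined were the groups, comparisons, tests, thresholds, gene lists, the naming rule and the first list of alternatives. The plan foresaw a count model for raw counts and limma for TPM, and the unit decided for limma.

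Gene lists, 34 in all, covered macrophage programs, other cell types and RNA quality. A list needed 4 tested members. They were tested with camera at a preset inter-gene correlation of 0.01, and again with a correlation estimated from the residuals, adjusted over the lists of a comparison. Within a list, calls were also counted with p adjusted over its members alone. Mitochondrially encoded genes had no members in these tables, and histones were tested in mouse only.

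Genes named in the text follow a rule. Part 1 takes the 5 largest rises and 5 largest falls of a comparison among called genes with at least 5 TPM in a group, whose groups do not overlap (not asked of interactions), leaving out predicted or clone names. Part 2 takes up to 4 members per list with the smallest p among those called, or 2 where none was. Part 3 is Jun, Fosl1, Slc2a1, Myd88, Il1b, Tnf, Hmox1 and Hk2. Genes past the threshold outside the rule are said to be so. Some genes that the rule names are not reported here. In human cells, HLA genes and genes that could tell a person's sex were left out everywhere. Reads shared by paralogs, or by short transcripts that lie inside other genes, may have been split in ways the sources used here do not give, so such genes are uncertain.

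The replicate numbers were checked for pairing by correlating deviations from group means. In the BMDM set all 9 same-numbered pairs correlated above 0.1 (median 0.408, lowest 0.102), against a median of -0.192 for other pairs, so there the numbers pair the samples. In the other sets some same-numbered pairs correlated below 0, so the numbers did not pair all samples. Same-numbered pairs still had the higher median in the inhibitor set (0.196 against -0.1) and the siRNA set (0.178 against -0.156). Numbers therefore carry some shared structure there. In the inhibitor set, deviations pointed to 2 batches, numbers 1 to 3 and 4 to 6, which the labels do not name.

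Alternatives planned before the data were examined were log2(TPM + 0.1), no low-value filter, no trend, no fold threshold, only the groups compared, a replicate block, each library left out in turn, quantile normalization and libraries with conflicting labels left out. Chosen after seeing the data were quantile normalization of the tests of lists and of targeted genes, voom on recovered reads, a batch term, each batch alone, libraries averaged over the batches, and replicates 2 and 5 of vehicle PBS and MSU left out. The limma calls and camera with the preset correlation were tested on simulated data with 200 changed genes per comparison. Noise was drawn independently for each gene and library, without the batches, pairs or partner libraries of the real data. The fit called 85 to 100% of 4-fold changes and 17 to 40% of 2-fold changes, with 0 to 9 unchanged genes called and 0 in the wrong direction. These counts do not cover false calls from libraries that deviate together. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6 and drawn with matplotlib 3.10.9.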

Results

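Polyadenylated RNA was sequenced in 116 libraries in 30 groups, 99 from mouse bone marrow-derived macrophages (BMDM) and 17 from human cells that the labels call mDM. Cells received PBS as the untreated control, lipopolysaccharide (LPS, a bacterial ligand of Toll-like receptor 4) or monosodium urate crystals (MSU, the crystals that form in joints in gout) for 5 h. The BMDM set held 3 libraries each with PBS, LPS and MSU, and the mDM set held 5 with PBS, 7 with LPS and 5 with MSU. In the inhibitor set, BMDM were given vehicle (6 PBS, 4 LPS and 6 MSU libraries), the JNK inhibitor SP600125 (6, 6 and 5) or BAY-876 (6, 6 and 6), called JNKi and Bay here. BAY-876 blocks the glucose transporter SLC2A1. In the siRNA set, BMDM were treated with siControl (3, 3 and 3), siJun (2, 3 and 2) or siFosl1 (2, 2 and 2) in the same order of agents. The Myd88 set compared wild-type BMDM (2, 3 and 3) with Myd88 knockout BMDM (3, 3 and 3), Myd88 being the adaptor of most Toll-like receptors and of the interleukin-1 receptor. Reads recovered from the values ran from 4.62 to 19.7 megareads (M) per library in the BMDM set, 2.08 to 15.7 in mDM, 3.23 to 20.8 in the inhibitor set and 8.08 to 24.6 in the Myd88 set. They ran from 10.3 to 39.3 M for siControl, 9.66 to 57.9 for siJun and 6.24 to 53.6 for siFosl1, with 1 library in each of the latter not resolved. The labels do not say whether replicates are separate cultures, animals or donors, so every p-value measures the spread between these samples. Values are TPM as mean ± SD, and numbers in parentheses after gene symbols are log2 fold changes.

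The targeted genes were read first, because they check the labels of the siRNA and knockout libraries. Percents of control or wild type here come from the fold change of log2(TPM + 1) values. They therefore differ somewhat from the ratio of the TPM means beside them. Jun (mm10 chromosome 4, 95049036 to 95052222, minus strand), which encodes the AP-1 subunit c-Jun, was at 38.8 ± 1.20 against 97.5 ± 17.5 TPM with siJun and siControl in MSU (n = 2 and 3), 40.8% of control (adjusted p = 0.0427). That call is fragile: the fold stayed about as large, but the adjusted p was 0.0531 with quantile-normalized values (-1.32), 0.0792 with a replicate block, 0.108 on recovered reads and 0.256 in a fit of these groups alone, and over 0.05 with any of the 5 libraries left out. In LPS the same siRNA left 40.6% (11.7 ± 2.43 against 29.98 ± 3.89 TPM, n = 3 and 3, adjusted p = 0.00539), and in PBS Jun did not pass the threshold at 96.5% (43.3 ± 4.55 against 47.6 ± 21.3 TPM, n = 2 and 3). Fosl1 (chromosome 19, 5447698 to 5455938, plus strand), which encodes the AP-1 subunit Fra-1, was at 11.8 ± 2.24 against 33.3 ± 2.55 TPM with siFosl1 and siControl in MSU (n = 2 and 3), 37.1% of control (adjusted p = 4.64e-04, but 0.229 in a fit of these groups alone). In PBS and LPS Fosl1 stayed under 1 TPM in the siControl and siFosl1 groups, so a knockdown there was not detectable. Myd88 (chromosome 9, 119335988 to 119340040, minus strand) was at 17.2 ± 2.39 against 68.9 ± 6.44 TPM in knockout and wild-type PBS libraries (n = 3 and 2), 25.9% of wild type (adjusted p = 5.04e-05). The knockout kept 15.6% in LPS and 25.2% in MSU (adjusted p = 4.61e-09 and 1.15e-05). The labels do not give the deleted part of the gene, so transcript that remains does not by itself question the knockout.

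**Figure D1:**
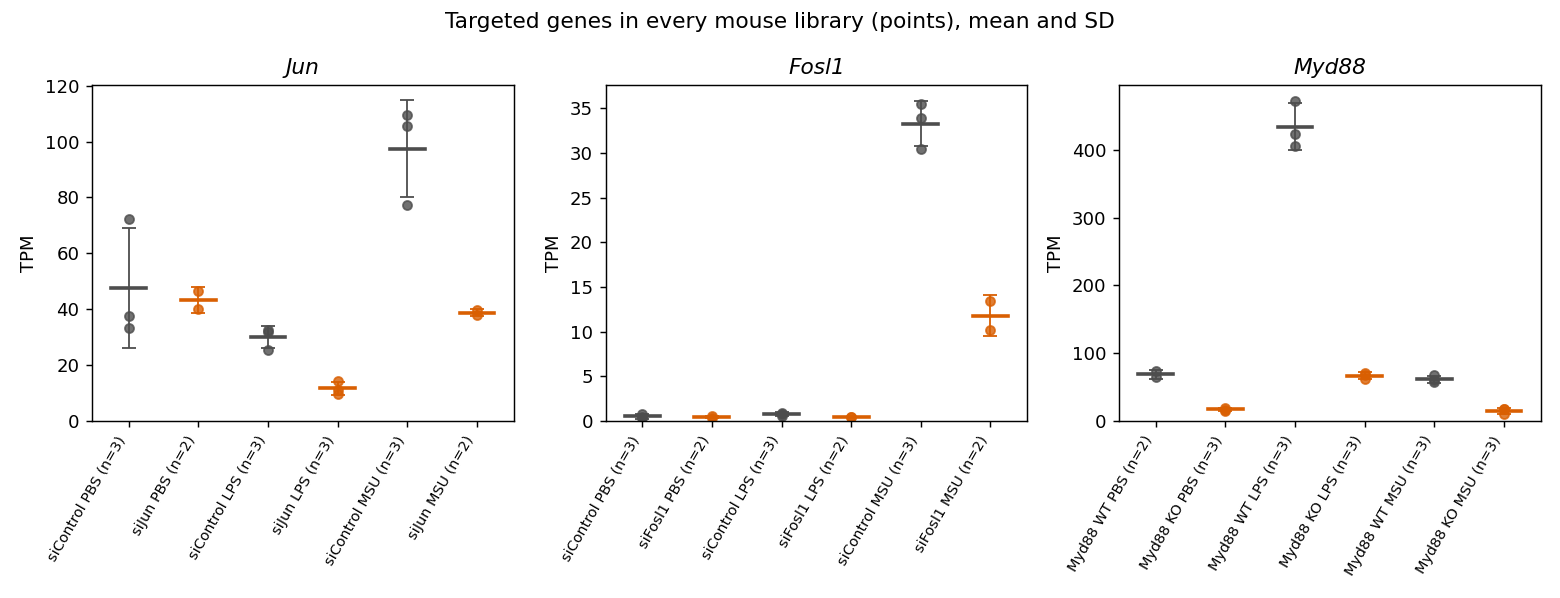
Jun, Fosl1 and Myd88 in every library of the siRNA and Myd88 sets, in TPM, with points for libraries and lines and bars for the group mean and SD. In MSU the siJun libraries lie below siControl for Jun and the siFosl1 libraries for Fosl1, and each knockout library lies below wild type for Myd88.

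The comparison of MSU with PBS asks how a macrophage answers crystals alone. In mouse BMDM, MSU raised the AP-1 gene Fosl1 (4.35), from almost no transcript to 30.9 ± 5.12 against 0.558 ± 0.232 TPM (n = 3 and 3). Other bZIP genes rose with it, Maff (4.43), Fosb (3.84), Mafk (2.62) and Jun (1.53) among them. So did the immediate early genes Nr4a2 (3.84), Egr2 (3.44), Nr4a3 (3.38) and Klf4 (3.18), which a stimulus switches on without new protein synthesis. The phosphatase genes Dusp10 (4.11), Dusp1 (3.49), Dusp4 (3.35) and Dusp14 (2.67), which switch MAP kinases off, rose too. Stress programs rose too. The NRF2 targets Txnrd1 (3.55), Srxn1 (3.39), Hmox1 (3.31) and Sqstm1 (2.82), which encode 2 antioxidant enzymes, heme oxygenase 1 and the autophagy receptor p62, were among them. The integrated stress response genes Gdf15 (5.58), Chac1 (3.98), Ppp1r15a (3.27) and Atf4 (2.54) rose with the amino acid transporter genes Slc7a5 (3.06) and Slc7a1 (2.53). The glucose transporter gene Slc2a1 (chromosome 4, 119108745 to 119137329, plus strand) rose from 30.1 ± 5.73 to 229 ± 19.3 TPM, together with the glycolysis genes Pfkfb3 (1.86) and Hk1 (1.79). Among secreted factors, Cxcl2 (5.48), Cxcl1 (3.70), Ccl3 (3.40), Tnf (2.54), Hbegf (3.51) and Il1rn (5.31) rose, whereas Il1b did not pass the threshold (0.40, adjusted p = 0.818). The apoptotic-cell receptor gene Mertk (-2.66), the macrophage transcription factor gene Maf (-2.83), the endosomal receptor genes Tlr8 (-2.87) and Tlr9 (-1.93), the prostaglandin-degrading enzyme gene Hpgd (-3.66) and the urate transporter gene Slc2a9 (-1.36) fell. In limma, 2033 of 11748 genes passed, 769 risen and 1264 fallen, around a median of -0.25 over all tested genes, and with quantile-normalized values 1013 rose and 819 fell. Of the fixed lists, 12 of 21 NRF2 targets, 11 of 13 integrated stress response genes and 9 of 13 AP-1 and related bZIP genes rose. So did 9 of 13 genes of negative MAP kinase feedback and 10 of 15 immediate early genes, all the same counts adjusted over the list alone. Camera put 17 of 30 lists past the threshold and 0 with an estimated correlation, the lowest being adjusted p = 0.101 with an estimated correlation for NRF2 targets (1.05e-12 with the preset one). Lists of other cell types and of RNA quality moved little: 1 of 5 neutrophil markers and 1 of 5 replication-dependent histones fell, and 0 of 9 fibroblast and stromal markers passed. With the replicate number as a block camera put 19 lists past the threshold, the fibroblast list (adjusted p = 0.0288) and LXR targets (0.0391) being added, and 0 with an estimated correlation.

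LPS gave the same cells a cytokine and interferon response. The inducible nitric oxide synthase gene Nos2 (8.13) rose most, followed by the interferon-induced chemokine gene Cxcl10 (7.77), the itaconate synthase gene Acod1 (7.67) and Il1b (7.67), which encodes the precursor of interleukin-1 beta. Tnf reached 1647 ± 324 against 38.6 ± 28.01 TPM (n = 3 and 3), and the NF-kappaB regulators Tnfaip3 (4.94), Nfkbia (3.46) and Nfkb1 (2.61) rose with it. The interferon pathway genes Stat2 (3.55) and Ddx58 (4.50) and the inflammasome genes Nlrp3 (3.80), Casp4 (4.27) and Il18 (3.55) rose, as did Slc2a1 (2.36) and Pfkfb3 (3.47). Fosl1 did not pass (0.75), and Jun fell (-1.13), although with quantile-normalized values its fold of -0.88 missed the fold threshold. The chemokine receptor gene Cxcr4 (-5.98) and the myeloid factor gene Cebpa (-5.40) fell. The sterol genes Hmgcs1 (-2.39), Stard4 (-2.99) and Insig1 (-2.18) of synthesis, transport and control, the replication genes Mcm2 (-2.41) and Mcm3 (-2.40) and the lysosome regulators Tfeb (-2.69) and Flcn (-2.94) fell as well. Of 11748 genes, 1199 rose and 4569 fell around a median of -0.78, and 1686 rose and 1908 fell with quantile-normalized values. All 27 interferon-stimulated genes and all 21 NF-kappaB targets rose, also adjusted over the list alone (camera adjusted p = 8.41e-27 and 3.89e-19; adjusted p = 0.185 with an estimated correlation for each).

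Set directly against LPS, MSU gave higher Fosl1 (3.61), Jun (2.66), Hmox1 (2.95), Gclc (4.52), Vegfa (4.10), Gdf15 (4.91), Nr4a2 (3.83) and Dusp10 (3.72). The urokinase gene Plau (4.05), the lipid-sensing receptor gene Pparg (4.13) and the scavenger receptor gene Cd36 (2.21) were also higher. LPS gave the higher Nos2 (-8.01), Il6 (-7.74), Il1b (-7.26) and Tnf (-3.06), the higher interferon genes Ddx58 (-4.43), Herc6 (-4.56) and Cxcl9 (-6.18) and the higher receptor genes Tlr3 (-5.44), Fcgr1 (-4.43) and Msr1 (-3.16). The regulators of lysosomes Flcn (3.27) and Tfeb (2.24) and the sterol genes Sqle (3.33) and Insig1 (2.47) were also higher with MSU, and Nlrp3 (-2.46), Gsdmd (-2.39) and Il18 (-5.02) of the inflammasome list were lower. In limma 3122 genes were higher and 1189 lower with MSU (median 0.53), and 1634 and 1536 with quantile-normalized values. All 27 interferon-stimulated genes were lower, and 16 of 21 NRF2 targets and 19 of 28 lysosome genes were higher, the same counts adjusted over the list alone (adjusted p = 0.319, 0.442 and 0.319 with an estimated correlation). MSU and LPS were each compared with the same PBS libraries, so their fold changes share chance values: across genes they correlated at 0.423, where unchanged simulated groups gave 0.503. The covariance was 0.491 against a simulated 0.0395, a difference of 0.452. Calls overlapped at 255 genes that rose with both agents (78.5 for independent lists). A further 136 rose with MSU and fell with LPS (299 for independent lists). Part of the excess may come from the shared controls, and the overlap of 0 in unchanged simulated groups, which call almost no genes, does not bear on it.

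**Figure D2:**
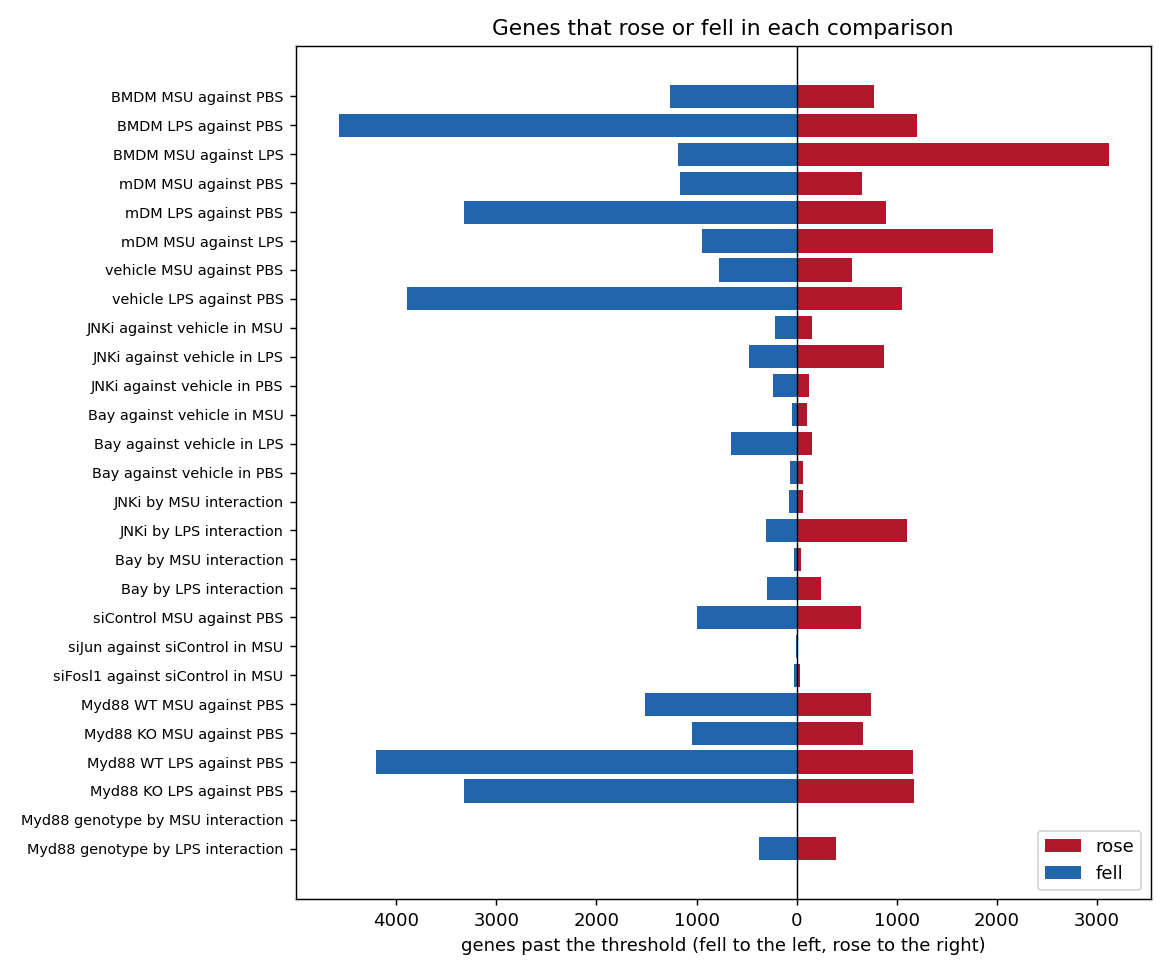
Genes past the threshold in each of the 27 comparisons, fallen to the left and risen to the right of 0, as a count of genes. LPS comparisons hold the longest bars to the left, and the siJun, siFosl1 and genotype by MSU comparisons are close to 0.

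In human mDM, MSU raised immediate early genes, among them ARC (6.59), FOSB (6.48), NR4A2 (6.26), EGR1 (5.36), NR4A1 (4.72), KLF4 (4.89) and EGR2 (2.50), and HES1 of the Notch pathway (5.63). The AP-1 genes JUN (2.64), FOSL1 (2.49), FOS (3.29), ATF3 (4.34) and MAFF (4.05) rose, JUN to 477 ± 162 against 71.8 ± 7.80 TPM (n = 5 and 5), and so did DUSP5 (4.72), DUSP4 (4.04) and DUSP1 (3.39). Growth factor genes that rose included INHBA (4.18), AREG (4.09), LIF (3.78) and HBEGF (3.25), along with CXCL2 (5.39), CCL20 (4.01), PTGS2 (3.94) and GDF15 (2.52). Of tissue remodelling and growth factor genes, 9 of 21 rose and 1 fell, the same adjusted over the list alone (adjusted p = 0.0346 with an estimated correlation). The stress genes PPP1R15A (2.90), ATF4 (1.64) and TXNRD1 (1.37) rose as well, and SLC2A3 (2.43) rose among glucose transporters. SLC2A1 rose by 1.22 (adjusted p = 0.0336), a call that ended when any of 6 libraries was left out, at 1.06 to 1.28 (adjusted p from 0.0507 to 0.0848), and IL1B, TNF and HMOX1 did not pass. That depends on the choice of libraries and fit: without the PBS library with a conflicting organism label, which stood far above the others in IL1B and TNF, IL1B (2.00, adjusted p = 0.0118) and TNF (1.88, 0.0208) passed, and HMOX1 did so in a fit of these groups alone (1.13, 0.0331). The adenosine receptor gene ADORA3 (-3.04), MERTK (-1.94) of macrophage identity, the osteoclast receptor gene TNFRSF11A (-1.88) and the receptor genes TLR4 (-1.50) and TLR6 (-1.64) fell. In limma 653 of 12130 genes rose and 1164 fell around a median of -0.38, and 833 rose and 381 fell with quantile-normalized values. Leaving out 1 library moved the fallen count between 701 and 1820, and the risen count between 562 and 706. Camera passed 19 of 28 lists, and 9 held with an estimated correlation. These included 13 of 15 immediate early genes risen (adjusted p = 0.00511), 10 of 14 AP-1 and related genes (0.00843) and 9 of 13 genes of MAP kinase feedback (0.0171), the same counts adjusted over the list alone. For chemokines (6 of 16) and NF-kappaB targets (5 of 21) the call was lost, at adjusted p = 0.101 and 0.185 with an estimated correlation, and 1 of 5 dendritic cell markers, CCR7 (2.92), rose.

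LPS raised IDO1 (7.95), which encodes the enzyme that degrades tryptophan, and the antiviral genes RSAD2 (7.60), CXCL10 (7.36), CXCL11 (6.78), CMPK2 (5.80) and USP18 (5.12) in mDM, with IL1B at 2212 ± 1507 against 308 ± 523 TPM (n = 7 and 5). In 1 PBS library IL1B stood at 1242 TPM and in the next highest at 94.2, so that library alone sets most of the PBS mean. The costimulation gene CD40 (4.35), the cytokine genes CSF3 (4.26), IL10 (3.29) and TNF (2.63), the itaconate synthase gene ACOD1 (6.69) and SLC2A1 (1.35) and PFKFB3 (3.28) rose. FOS moved opposite to its MSU response (-3.05), and ADORA3 (-5.22), MERTK (-4.97), PLIN2 (-3.46), TXNIP (-2.21) and HMOX1 (-1.99) and the lysosome genes TFEB (-2.39) and ATP6V0A1 (-2.43) fell. Of 12130 genes 890 rose and 3325 fell (median -0.64), with 1288 and 1121 after quantile normalization. 25 of 27 interferon-stimulated genes and 19 of 21 NF-kappaB targets rose, the same adjusted over the list alone (camera adjusted p = 1.38e-36 and 2.96e-18; adjusted p = 0.0715 with an estimated correlation for each). Against LPS, MSU gave higher FOSB (6.75), EGR1 (6.49), FOS (6.34), NR4A1 (6.34), JUN (3.28), FOSL1 (2.40), HMOX1 (3.12), PLIN2 (5.04) and HBEGF (4.32). Lower were IDO1 (-7.40), RSAD2 (-6.86), CXCL10 (-6.78), CD40 (-4.45), IL1B (-2.73) and MYD88 (-2.28). In limma 1963 genes were higher and 950 lower around a median of 0.28 (1337 and 1232 with quantile-normalized values). There 12 of 15 immediate early genes were higher and 26 of 27 interferon-stimulated genes lower, also adjusted over the list alone (adjusted p = 0.200 and 0.147 with an estimated correlation). The MSU and LPS responses of mDM correlated at 0.388 across genes, against 0.541 in unchanged simulated groups that share the PBS libraries, with a covariance of 0.327 against 0.0449 and a difference of 0.282.

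Of 8984 genes tested in mouse and human under the same symbol, 185 rose with MSU in both species, where independent lists would share 28.6. Of 602 genes that rose in mouse, 29 fell in human, where 843 of all 8984 genes fell. Such opposite calls were thus rarer than for independent lists. Among falls, 131 were shared (88.7 for independent lists), and fold changes correlated at 0.369 across genes, which are not independent replicates. Another 15 genes of 945 that fell in mouse rose in human, Hpgd (-3.66 and 1.20) and Slc2a3 (-1.28 and 2.43) among them. In human 427 of all 8984 genes rose, so these were also rarer than for independent lists. Fosl1, Jun, Maff, Fosb, Nr4a2, Dusp4 and Hbegf were among the genes that rose in both species, and Mertk and Tnfrsf11a among those that fell. LPS gave 299 shared rises (52.3 for independent lists) and a correlation of 0.498. Of 849 genes that rose in mouse with LPS, 132 fell in human, where 2611 of all 8984 genes fell, again fewer than for independent lists. Symbols, not an orthology table, matched the species, and the difference between them was not tested.

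The MSU response was then followed in 3 further sets of untreated-arm BMDM. With vehicle, MSU raised Cxcl2 (5.19), Gem (4.87), Gdf15 (4.67), Rgcc (4.50) and Flrt3 (4.08) most and lowered Hpgd (-4.37), Abcd2 (-3.45), Ccr2 (-2.79), Mertk (-2.09) and Maf (-2.17). Fosl1 was at 5.25 ± 1.16 against 0.362 ± 0.208 TPM there (n = 6 and 6), and Jun (1.80), Slc2a1 (2.14), Hmox1 (3.13), Tnf (2.30), Atf4 (2.17) and Dusp4 (3.60) rose. With siControl the largest rises were Serpinb9b (5.84), Edn1 (5.70), Ptgs2 (5.24), Lrrc32 (5.20) and Cxcl1 (5.11). Regulators and cytokines that rose included Fosl1 (4.50), Fosb (4.44), Egr1 (3.33), Il10 (4.79), Hbegf (4.95) and Osm (4.08), and Saa3 (-3.55), Fpr1 (-3.50), Itgal (-3.25), Nr1h3 (-2.43) and Cx3cr1 (-2.76) fell. In wild-type cells of the Myd88 set, Cxcl2 (7.29), Il1rn (5.89), Ccl7 (5.75), Gem (5.47) and Cxcl1 (5.43) rose most, Tnf (4.32), Slc2a1 (3.85), Fosl1 (3.73), Dusp5 (4.94) and Inhba (4.24) rose too, and Hpgd (-3.97), Arrdc3 (-3.79), Mertk (-3.12) and Tlr9 (-2.24) fell. The 4 mouse sets shared 245 risen and 249 fallen genes of 10788 tested in all, and 31 rose in 1 set and fell in another. Of the shared rises, 204 were tested in human mDM, where 100 rose and 7 fell. Counts were 548 risen and 780 fallen with vehicle (741 and 466 with quantile-normalized values, median -0.23). They were 640 and 992 with siControl (874 and 624, median -0.24) and 746 and 1518 in wild type (1060 and 865, median -0.28). Genes risen in the BMDM set that were tested elsewhere rose again in 443 of 763 cases with vehicle, 391 of 716 with siControl and 510 of 757 in wild type. NRF2 targets rose in 12 of 21, 10 of 20 and 8 of 21 cases, the same adjusted over the list alone. Camera passed them in each set, with adjusted p = 0.0147, 0.368 and 0.126 with an estimated correlation. Genes of MAP kinase feedback rose in 8 of 13, 8 of 12 and 10 of 12 cases (adjusted p = 3.62e-04, 0.00955 and 0.0110 with an estimated correlation). LPS with vehicle raised Ptgs2 (7.28), Il1a (7.22), Il1b (7.19) and Nos2 (7.01) and lowered Cxcr4 (-7.07), Susd3 (-5.99), Jun (-1.83), Mertk (-2.78) and Tlr13 (-3.35). It gave 1047 risen and 3890 fallen genes (median -0.61, with 1519 and 1634 on quantile-normalized values), and 21 of 21 NF-kappaB targets rose (adjusted p = 0.0199 with an estimated correlation).

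The JNK inhibitor asks which part of the MSU response needs JNK, the kinase that phosphorylates c-Jun. In MSU-treated BMDM it lowered Fosl1 from 5.25 ± 1.16 to 1.01 ± 0.278 TPM (n = 6 and 5), and with it Tnf (-2.16), Cxcl2 (-2.01), Ccl3 (-2.03), Ccl4 (-2.35), Ccl2 (-1.81), Plaur (-1.41) and Maff (-1.19). The NRF2 targets Srxn1 (-1.87), Txnrd1 (-1.60), Hmox1 (-1.36), Gsr (-1.26) and Prdx1 (-1.25), the inflammasome genes Nlrp3 (-1.13) and Panx1 (-1.63) and the itaconate synthase gene Acod1 (-2.81) fell. So did the interferon-stimulated genes Ifit3 (-2.54), Ifit1 (-2.38), Rtp4 (-2.53), Parp14 (-1.79) and Oas2 (-1.74). Genes of the integrated stress response and of serine synthesis rose instead, Atf5 (2.24), Trib3 (2.30), Sesn2 (1.66), Phgdh (2.20), Shmt2 (2.17) and Asns (1.61) among them, as did Thbs1 (2.66), Dio2 (2.53) and Sox4 (2.32). Slc2a1 and Jun did not pass (-0.82 and -0.24). In limma 152 genes rose and 219 fell of 12659 (median -0.02). Libraries numbered 1 to 3 and 4 to 6 (1 to 2 and 3 to 4 for vehicle LPS) differed as 2 batches do. All 60 named genes called here kept their direction in each batch, and 55 of them passed in both. Here and below these genes were called in the fit that holds both batches. A kept direction is therefore nearly given by the choice and is no separate evidence. In all 20 of 27 interferon-stimulated genes fell (adjusted p = 0.198 with an estimated correlation), with 22 in the first batch and 10 in the second. With an estimated correlation, 7 of 21 NRF2 targets fell (adjusted p = 0.0338), while 7 of 13 integrated stress response genes (0.00179) and 7 of 15 genes of serine and amino acid supply (0.00399) rose, all the same adjusted over the list alone.

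Whether the inhibitor changes the MSU response itself is a question for the interaction, which subtracts the effect of JNKi in PBS. There Fosl1 (-1.58), Hmox1 (-1.98), Srxn1 (-1.60), Gdf15 (-2.14), Cxcl2 (-1.94), Prdx1 (-1.35), Osgin1 (-1.39), Plaur (-1.38) and Ampd3 (-1.18) responded less to MSU with JNKi. Responses were larger for Nr4a1 (2.06), Egr3 (1.96), Egr1 (1.56), Nr4a2 (1.30), Plau (1.33) and Lpl (2.03). For Nr4a1, Egr3, Egr1, Plau and Lpl they start from a PBS level that JNKi lowered. A larger response is not a higher level: in MSU itself Egr1 was lower with JNKi (-1.48). Gdf15, in turn, started from a PBS level that JNKi raised (2.66). Tnf passed in the interaction as well (-1.38) but in neither batch alone. In limma it was at -1.55 in the first (adjusted p = 0.118) and -1.15 in the second (adjusted p = 0.151). Of all tested genes 134 passed, 58 higher and 76 lower, a count that 11 of 100 splits of these libraries reached. Splits that part JNKi and vehicle libraries unevenly carry the effects of JNKi in PBS and MSU into the interaction. The splits therefore do not decide chance, which is not excluded for the count. NRF2 targets were lower in 8 of 21 cases, the same adjusted over the list alone (adjusted p = 7.62e-04 with an estimated correlation). In PBS alone JNKi raised Atf5 (3.08), Gdf15 (2.66), Trib3 (2.64), Thbs1 (2.48), Asns (2.06) and Phgdh (2.04) and lowered Egr1 (-3.04), Egr3 (-2.33), Nr4a1 (-2.39), Lpl (-2.84), Spred2 (-2.05) and Plau (-2.17). The counts there were 127 risen and 237 fallen genes (177 and 199 with quantile-normalized values, median -0.09). Among them 23 of 27 (24 adjusted over the list alone) interferon-stimulated genes fell (adjusted p = 0.240 with an estimated correlation). All 46 named genes kept that direction in each batch. In LPS JNKi raised Mmp9 (3.94), Cxcl3 (3.51), Arg1 (3.45), Nr1h3 (3.25), Shmt2 (3.59), Chac1 (3.44) and Egln3 (2.77) and lowered Il10 (-4.08), Tnfsf4 (-4.65), Rsad2 (-3.94), Inhba (-2.14), Dusp1 (-2.29) and Cxcl11 (-3.65). It gave 871 risen and 477 fallen genes around a median of 0.29, but 371 and 615 with quantile-normalized values. Hmox1, which fell in MSU, rose there (2.21), and the interaction with LPS was positive for it (1.59). 21 of 27 interferon-stimulated genes fell with JNKi in LPS, the same adjusted over the list alone (adjusted p = 0.125 with an estimated correlation), and 12 of 15 genes of serine supply rose (adjusted p = 0.0291). The JNKi by LPS interaction held 1104 higher and 307 lower genes (378 and 551 with quantile-normalized values, median 0.38). It was higher for Mmp9 (3.90), Cx3cl1 (3.03), Pdk1 (2.50), Spred2 (2.56) and Stard4 (2.82) and lower for Il10 (-3.93), Lhx2 (-3.77) and Il1a (-2.53). Cholesterol synthesis genes were higher in 18 of 21 cases, the same adjusted over the list alone (adjusted p = 0.358 with an estimated correlation). All 87 named genes called in LPS, 30 in the MSU interaction and 87 in the LPS interaction kept their direction in each batch, which their choice from both batches favours.

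BAY-876 tests whether glucose uptake through SLC2A1 shapes the response. In MSU it lowered Txnip (-2.56), a gene that glucose-sensing MondoA switches on, from 118 ± 4.09 to 19.5 ± 4.30 TPM (n = 6 and 6). The deiodinase gene Dio2 (2.59), the growth factor genes Pgf (1.71) and Pdgfa (1.34) and the matrix protease genes Mmp19 (1.83), Mmp13 (1.29) and Mmp14 (1.18) rose, as did Cxcl3 (1.61), Serpinb6b (1.88) and Ctsk (1.10). Falls included Trnp1 (-1.69), Mxd4 (-1.43), Cnnm4 (-1.32) and Hist1h2bc (-1.51). Fosl1 rose by 1.08 (adjusted p = 1.25e-08) and Gdf15 by 1.27. Without replicates 2 and 5 of vehicle PBS and vehicle MSU, which stood apart from their groups, the folds were 0.90 and 0.98 and missed the fold threshold. For Fosl1 the fold was also just short of it without vehicle MSU replicate 5 and in the first batch alone (0.99 in each). Slc2a1 and Tnf did not pass (0.51 and -0.45). In limma 103 genes rose and 52 fell (median -0.20), 169 and 15 with quantile-normalized values, and 73 passed without those libraries. Leaving out 1 library moved the risen count between 82 and 113 and the fallen count between 34 (without vehicle MSU replicate 2) and 80 (without replicate 4 or 6). The balance also depends on the scale and the threshold, with 162 risen and 342 fallen with log2(TPM + 0.1), 182 and 313 with voom on recovered reads, and 1411 and 6218 with no fold threshold. Of tissue remodelling and growth factor genes, 4 of 20 rose, the same adjusted over the list alone (adjusted p = 0.00612 with an estimated correlation). Read from the interaction, the response to MSU was larger with Bay for Csf1 (1.64), Pgf (1.63), Serpinb1a (1.50), Trib3 (1.43) and Chac1 (1.30) and smaller for Txnip (-2.30) and Angptl4 (-1.49). Fosl1 passed at 1.15, but missed the fold threshold without those libraries (0.85). The interaction held 46 higher and 27 lower genes, and 40 of either direction without those libraries. Of genes of serine and amino acid supply 3 of 15 were higher, the same adjusted over the list alone (adjusted p = 0.00127 with an estimated correlation). In PBS Bay raised the chemokine receptor gene Ccr2 (1.96) with Gpr34 (1.78) and Gpr162 (1.77) and lowered the interferon-stimulated genes Ifit1 (-1.94) and Gbp7 (-1.73). There 59 genes rose and 63 fell (119 and 40 with quantile-normalized values, median -0.16). 17 of 27 interferon-stimulated genes fell, the same adjusted over the list alone (adjusted p = 0.481 with an estimated correlation), but 1 in the first batch and 21 in the second. In LPS Bay lowered Txnip (-3.15), Csf2 (-2.98), Hmgcs1 (-2.01), Msmo1 (-1.90), Pdgfb (-1.85) and Slc1a5 (-1.61) and raised Gpr141 (2.56), Plac8 (2.08), P2ry13 (2.02), Mertk (1.85), Abcg1 (1.76), Cxcl9 (1.49) and Jun (1.09). It gave 157 risen and 661 fallen genes around a median of -0.32, but 302 and 60 with quantile-normalized values. The Bay by LPS interaction was higher for Ifit2 (2.94), Ifit1bl1 (2.71), Mx2 (2.08), Cxcl9 (1.87) and Ifih1 (1.44) and lower for Csf2 (-2.98), Txnip (-2.89), Pdgfb (-2.64), Hmgcs1 (-2.23) and Pdgfa (-1.43). It held 241 higher and 294 lower genes (307 and 97 with quantile-normalized values, median -0.22). Interferon-stimulated genes were higher in 20 of 27 cases, the same adjusted over the list alone (adjusted p = 0.236 with an estimated correlation), with 7 in the first batch and 22 in the second. This reflects the fall with Bay in PBS: in LPS itself Bay moved the list by a median of 0.27, with 2 of 27 risen and 0 fallen. Every named gene called in these 5 comparisons kept its direction in each batch, which the choice of these genes from both batches favours. In both batches 18 of 24 passed for MSU, 10 of 21 for PBS and 36 of 51 for LPS. JNKi and Bay effects in MSU share the vehicle libraries and correlated at 0.319 across genes, against 0.476 in unchanged simulated groups and a mean of 0.227 over 20 ways to split the vehicle libraries. Their covariance was 0.0448 against a simulated 0.0112, and 22 genes rose and 17 fell with both (1.24 and 0.900 for independent lists). Each effect was then tested against 3 of the vehicle libraries that the other did not use. A mean of 22.4 genes rose with both (16 to 26 over the splits) and 15.2 fell (5 to 30). Independent lists would share 1.27 and 1.36, although those libraries can be partners.

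**Figure D3:**
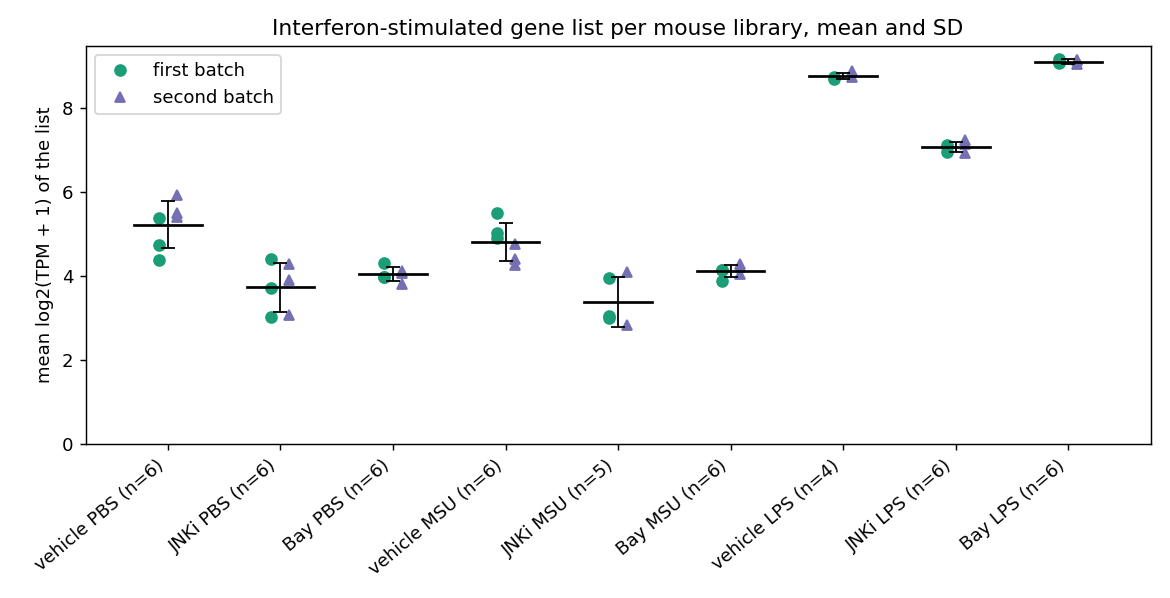
Mean log2(TPM + 1) of the 27 interferon-stimulated genes in each library of the inhibitor set, with points shaped by batch and lines and bars for the group mean and SD. In PBS the vehicle libraries spread from 4.38 to 5.92, and the Bay libraries lie between 3.79 and 4.31.

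Silencing Jun in MSU-treated BMDM put few genes beyond Jun itself past the threshold. On simulated data the same fit called 98% of 4-fold but 35% of 2-fold changes, which lie at the fold threshold. On the adjusted p alone 78% of the 2-fold changes passed. Changes of about 2-fold could therefore go uncalled, and estimates under 2-fold cannot be called. In the main limma fit 1577 genes had an unadjusted p under 0.05. Fosl1 was at 16.4 ± 0.351 against 33.3 ± 2.55 TPM with siControl (n = 2 and 3). On log2(TPM + 1) values this was 50.9% of siControl (limma adjusted p = 0.0424), just short of the fold threshold at -0.98. So small a miss depends on the 1 TPM added before the log. Of 11528 genes 10 passed, 6 risen and 4 fallen, among them S100a1 (1.16), which encodes a calcium-binding protein, and Gprc5a (-1.15), a receptor gene. In limma 0 passed in a fit of these groups alone and 0 on recovered reads (1398 and 1306 at an unadjusted p under 0.05). Leaving out siControl MSU replicate 1 left 4 and replicate 2 left 2 (13 without siJun MSU replicate 1). The lists that passed camera, such as AP-1 and related genes with 1 of 14 fallen, did not hold (adjusted p = 0.125 with an estimated correlation). Silencing Fosl1 raised Csf2 (1.92), the gene of the growth factor GM-CSF, along with Mmp8 (1.16) and Batf3 (1.53), and lowered Tm4sf19 (-1.55) and Adm (-1.10), the last being the vasodilator adrenomedullin, next to Fosl1 itself. It passed 60 of 11528 genes, 32 risen and 28 fallen, several of them short microRNA and snoRNA host transcripts such as Mir425 (3.02) and Mir7077 (-4.10). In limma 0 passed in a fit of these groups alone (1404 at an unadjusted p under 0.05), 24 did so on recovered reads, and the count was 121 without siFosl1 MSU replicate 2. Of the 2 siFosl1 MSU libraries 1 carries conflicting labels, and without it and an LPS library of the same kind 66 genes passed, 22 of them among the 60, while Csf2, Tm4sf19, Mir425 and Mir7077 kept their direction but lost their calls. NF-kappaB targets passed camera (adjusted p = 5.98e-04; adjusted p = 0.894 with an estimated correlation), with 1 of 22 risen, the same adjusted over the list alone. Each siRNA came in a file of its own, so a difference between files cannot be told apart from the siRNA. By interaction with MSU, 0 genes passed for siJun in limma (956 had an unadjusted value under 0.05) and 6 for siFosl1. The siJun interaction subtracts the difference in PBS, where no knockdown of Jun was detected.

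The Myd88 knockout asks whether crystals act through this adaptor. In knockout BMDM MSU still raised Cxcl2 (7.16), Ccl7 (5.19), Csf1 (5.08), Il1rn (5.07), Gem (5.05), Tnf (4.03), Slc2a1 (3.17), Fosl1 (3.15), Jun (1.36) and Hmox1 (1.46). Fosl1 was at 10.4 ± 3.99 against 0.235 ± 0.0680 TPM (n = 3 and 3), and Nr4a1 (4.31), Nr4a2 (4.41), Egr2 (2.80), Dusp1 (4.59), Dusp5 (4.30), Gdf15 (4.09), Txnrd1 (2.58), Plau (3.38) and Inhba (3.83) rose with it. The genes Hpgd (-3.68), Arrdc3 (-3.50), Engase (-3.48), Bmf (-3.32), Mertk (-2.44), Maf (-2.24), Tlr8 (-1.98) and Cd163 (-1.95) fell. In limma 663 genes rose and 1045 fell (862 and 664 with quantile-normalized values, median -0.22). Rises covered 12 of 15 immediate early genes, 10 of 14 AP-1 and related genes and 10 of 12 genes of MAP kinase feedback, the same adjusted over the list alone (adjusted p = 0.0129, 0.00952 and 0.00952 with an estimated correlation). The genotype by MSU interaction passed 1 gene of 12391, Mir6977 (1.92, adjusted p = 0.0221), a short transcript chosen after its values were seen. Leaving out 1 library moved this count between 0 (without wild-type MSU replicate 2, knockout PBS replicate 2, or knockout MSU replicate 1 or 2) and 4 (without knockout PBS replicate 3), with 2 for each of the others. With quantile-normalized values 0 genes passed in limma (788 at an unadjusted p under 0.05). Camera put 5 of 31 lists past the threshold, all with a lower response in the knockout than other genes, and 0 with an estimated correlation. Of 757 genes that rose with MSU in the BMDM set, 65.7% lay below 0 in the interaction, against 39.5% of all genes. That test was chosen after results were seen (camera adjusted p = 0.0751 with an estimated correlation). For Fosl1, Tnf, Slc2a1 and Hmox1 the interaction was -0.58, -0.28, -0.68 and -0.50, none past the threshold. All are under the fold threshold, so differences of this size cannot be called at any p. On simulated data the same fit called 97% of 4-fold but 31% of 2-fold changes, which lie at that threshold. On the adjusted p alone 54% of the 2-fold changes passed, and smaller changes were not simulated.

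LPS depended on Myd88 for part of its response. In wild type it raised Saa3 (10.13), Nos2 (9.83), Cxcl10 (9.42), Il1b (8.52), Lcn2 (7.96), Mmp13 (8.69) and Slc2a1 (3.17). In the knockout it raised Cxcl10 (8.67), Cd69 (7.97), Ifit1bl1 (7.89), Acod1 (7.86), Isg15 (5.57), Ccl5 (6.84), Il1b (2.04) and Tnf (4.67). The interaction was negative for the acute-phase genes Lcn2 (-7.86), Saa3 (-7.61) and Hp (-5.21) and for Il1b (-6.48), Tnf (-1.74), Cxcl2 (-2.97), Ccl3 (-1.61), Tnip3 (-3.58) and Irak3 (-3.32). It was also negative for the matrix protease gene Mmp13 (-4.12) and for the glucose genes Slc2a1 (-2.12) and Pfkfb3 (-2.60). It was positive for Ifi208 (4.55), Rgs2 (3.92), Cxcr4 (3.27), Mertk (2.10), Abcg1 (2.12), Plau (3.11), Klf4 (2.05) and Tlr9 (1.97). Il1b stood at 2144 ± 66.8 TPM in wild-type and 25.3 ± 15.5 TPM in knockout LPS libraries (n = 3 and 3). In limma 395 genes had a higher and 375 a lower response (285 and 405 with quantile-normalized values, median 0.13). LPS raised 1160 and lowered 4197 genes in wild type (1740 and 1833, median -0.67) and 1175 and 3318 in the knockout (1640 and 1536, median -0.57). NF-kappaB targets had a lower response in 14 of 20 cases, the same adjusted over the list alone (adjusted p = 0.00973 with an estimated correlation). Of interferon-stimulated genes 26 of 27 rose in wild type and 27 of 27 in the knockout, and by interaction 3 of 27 had a lower and 1 of 27 a higher response (adjusted p = 0.232 with an estimated correlation). For chemokines (8 of 18) and glucose transport and glycolysis (5 of 21) the call was lost at adjusted p = 0.110 and 0.156 with an estimated correlation.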

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

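In the second pattern below the tests of the batches and of the scaling were chosen only after the result was seen, as were both tests of the third pattern. Single libraries stood far from the rest of their group in 8 of 108 groups of values (7.41%), where chance gives about 5.4. In mDM PBS a library far above the others held FOSL1 at 20.4 TPM, IL1B at 1242 TPM and TNF at 366 TPM, and in mDM LPS a library held TNF at 1724 TPM. Vehicle MSU replicate 5 held Il1b at 31.3 TPM. Recovered reads stood apart in vehicle MSU replicate 6 (20.1 M), JNKi LPS replicate 6 (20.8 M) and Bay MSU replicate 6 (3.23 M).

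Effects of some groups differed by interaction in limma. The JNKi by MSU interaction called 134 genes, among them Fosl1 (-1.58), Tnf (-1.38) and Hmox1 (-1.98), but 11 of 100 splits of these libraries, the real one included, gave as many, and Tnf passed in neither batch alone. With partner pairs kept together, chance was not excluded for the counts of JNKi by MSU, Bay by MSU and Bay by LPS. For the JNKi by LPS count it was left unsettled, with 4 of 100 splits as high. Uneven splits can carry an inhibitor's own effects into the interaction, so these counts of splits do not decide chance. The response to LPS differed with JNKi for 1411 genes, Hmox1 (1.59) among them. With Bay, 73 genes differed in the response to MSU, Fosl1 (1.15) among them, and 535 in the response to LPS. With Myd88 knockout, 1 gene differed in the response to MSU and 770 in the response to LPS, among them Slc2a1 (-2.12), Il1b (-6.48), Tnf (-1.74) and Hmox1 (-1.17).

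Some comparisons of siRNA libraries with LPS or PBS were not among those above, and limma called genes there too. LPS with siControl changed 2815 genes against PBS. In LPS siJun changed 58 genes and siFosl1 18, and in PBS siFosl1 changed 1. In PBS siJun changed 0 genes in limma, with 192 at an unadjusted p under 0.05. Jun itself was at 96.5% of control in those libraries (43.3 against 47.6 TPM, n = 2 and 3). No knockdown was detected there, so this count does not show what silencing Jun does without a stimulus.

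The first pattern is the fall of most genes with LPS, with a BMDM median of -0.78. Genes near the floor were argued against in BMDM, since the median of 1916 genes with at least 50 TPM in PBS was -0.72. With vehicle that median was -0.54. In mDM it was -0.47, which missed the limit set beforehand for arguing against it. Genes that rose took 44.3 ± 0.874% of the listed TPM in LPS and 6.78 ± 0.638% in PBS, and the summed TPM of the other tested genes changed by -0.63, which follows from those shares and is no separate evidence. The medians were -0.64 in mDM and -0.61 with vehicle, with sums of the other genes at -0.53 and -0.55. A larger share of the risen genes and less RNA of the others cannot be told apart, since no known amount of RNA was added.

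The second pattern is the lower interferon-stimulated genes with Bay in PBS, 17 of 27 genes at a median of -1.11. In the batch with the smaller fall the median was -0.77, so the batch was argued against as the whole cause, although 1 gene passed in the first batch and 21 in the second. Quantile-normalized values left the median at -1.06, and leaving out vehicle PBS and MSU replicates 2 and 5 at -1.11. Vehicle PBS libraries spread widely in the list's mean (5.21 ± 0.556 log2 units, against 4.04 ± 0.169 with Bay). Against the same vehicle PBS libraries JNKi lowered the list too, at a median of -1.55 with 23 of 27 genes fallen. The fall is therefore not particular to Bay, and in PBS both falls rest on those libraries. Against vehicle MSU the list's median was -1.46 with JNKi (20 of 27 fallen) and -0.71 with Bay (3 of 27). In LPS the list's mean was 7.068 ± 0.112 with JNKi and 8.755 ± 0.0775 with vehicle (n = 6 and 4), while Bay moved its median by 0.27. A lower list with JNKi thus does not rest on the vehicle PBS libraries alone. An effect of BAY-876 on basal interferon signalling is a hypothesis, and cultures that differ in basal signalling stay open as untested.

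The third pattern is that libraries of the inhibitor set whose numbers differ by 3 (by 2 in vehicle LPS) deviated together. Of 25 libraries of the second batch, 21 correlated best with their partner, where permuted numbers gave 9.01 on average (one-sided permutation p = 2e-04 with 100000 resamples). Second libraries of the same RNA were argued against, since 8 of 25 partner pairs differed by over 0.5 log2 units from the median pair in the mean of the interferon-stimulated genes. These correlations are the pattern itself, so a shared day or source of cells, which the labels do not give, stays open, and no biological explanation was tested. Averaging the partners moved the JNKi count in MSU from 371 to 384 and the Bay count from 155 to 160.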

How the results depend on the processing

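Voom on recovered reads, the batch settings, the averaged partner libraries, quantile normalization of lists and targeted genes, and replicates 2 and 5 of vehicle PBS and MSU left out were chosen after seeing the data. Counts below are genes called, beside the main counts given above. Of the named genes called in the main fit or in the alternative, 0 changed direction under any alternative run, and 5 lists did. Changes of sign in genes called in neither were not counted.

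Without a fold threshold more genes pass by construction: 5406 for BMDM MSU, 9093 for BMDM LPS, 7908 for BMDM MSU against LPS, 5418 for mDM MSU, 8406 for mDM LPS, 6073 for mDM MSU against LPS, 5732 for siControl MSU, 20 for siJun, 136 for siFosl1, 6470 for wild-type MSU, 6270 for knockout MSU, 9367 for wild-type LPS, 9337 for knockout LPS and 1615 for genotype by LPS. In the inhibitor set these were 8968 for vehicle MSU, 10801 for vehicle LPS, 5604 for JNKi in MSU, 8725 for JNKi in LPS, 6382 for JNKi in PBS, 7629 for Bay in MSU, 8497 for Bay in LPS, 6989 for Bay in PBS, 2837 for JNKi by MSU, 8478 for JNKi by LPS, 2157 for Bay by MSU and 6571 for Bay by LPS. The balance of risen and fallen genes turned there, among others, for Bay in MSU, JNKi by MSU (1969 and 868) and Bay by MSU (846 and 1311), and with log2(TPM + 0.1) for Bay in MSU and siFosl1 (27 and 48).

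With log2(TPM + 0.1), which shrinks folds at low values less, the counts were 2926 for mDM MSU, 4 for siJun and 3 for genotype by MSU. In the inhibitor set they were 2088 for vehicle MSU, 675 for JNKi in MSU, 2284 for JNKi in LPS, 674 for JNKi in PBS, 504 for Bay in MSU, 2149 for Bay in LPS, 307 for Bay in PBS, 248 for JNKi by MSU, 2361 for JNKi by LPS, 144 for Bay by MSU and 1403 for Bay by LPS. Voom on recovered reads gave 3061 for mDM MSU, 2565 for siControl MSU, 0 for siJun, 24 for siFosl1 and 0 for genotype by MSU. In the inhibitor set it gave 2260 for vehicle MSU, 713 for JNKi in MSU, 2632 for JNKi in LPS, 690 for JNKi in PBS, 495 for Bay in MSU, 2295 for Bay in LPS, 331 for Bay in PBS, 260 for JNKi by MSU, 2500 for JNKi by LPS, 154 for Bay by MSU and 1634 for Bay by LPS. The cause of the differences with voom was not tested.

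Quantile normalization gave 3594 for BMDM LPS, 2409 for mDM LPS, 3153 for vehicle LPS, 362 for Bay in LPS, 929 for JNKi by LPS, 17 for siJun and 0 for genotype by MSU, and the cause was not tested beyond the shift of the medians in LPS. Jun with siJun in MSU kept its size (-1.32) but not its call (adjusted p = 0.0531). Direction turned for 5 lists in camera: lysosome and TFEB targets with Bay in PBS (adjusted p = 0.986), interferon-stimulated genes (0.814), lysosome and TFEB targets (0.817) and NF-kappaB targets (0.801) in JNKi by LPS, and oxidative phosphorylation subunits in wild-type LPS (0.0318). This setting changes the median of all genes, and the cause was not tested further. Camera called 339 lists over all comparisons, 307 with quantile-normalized values and 76 with an estimated correlation, which widens its spread.

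A replicate block left 2 genes for siJun and 0 for genotype by MSU, and moved no other count by over 1.5 times (2058 genes for BMDM MSU, 5797 for BMDM LPS and 4331 for BMDM MSU against LPS). Among named genes, 23 calls were lost and 3 gained with the block, 0 of them in the BMDM set. List tests were run with the block in the BMDM set only: fibroblast markers and LXR targets passed for MSU (adjusted p = 0.0288 and 0.0391), and integrated stress response and macrophage identity genes no longer passed for MSU against LPS (0.0754 and 0.0626), with no other list call changed. Outside the BMDM set the numbers did not pair all samples. The lowest same-number correlation was -0.444 in mDM, -0.259 in the inhibitor set, -0.569 in the siRNA set and -0.123 in the Myd88 set. The median was still above that of other pairs in the inhibitor set (0.196 against -0.1) and the siRNA set (0.178 against -0.156).

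In a fit of only the groups compared, 0 genes passed for siJun and 0 for siFosl1 (1398 and 1404 at an unadjusted p under 0.05), with fewer libraries to estimate the spread. Without the low-value filter 22 passed for siJun and 3 for genotype by MSU. In the first batch alone 79 passed for Bay in PBS, in the second alone 116 for Bay by MSU, and without replicates 2 and 5 of vehicle PBS and MSU 73 for Bay in MSU and 40 for Bay by MSU, and the cause was not tested. Leaving out libraries with conflicting labels, dropping the trend, a batch term and averaged partner libraries kept every count within 1.5 times, and without the libraries in conflict 22 of the 66 genes called for siFosl1 were among the 60 called before.

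With each library left out in turn, counts moved by over 1.5 times for siJun (2 to 13), siFosl1 (44 to 121) and genotype by MSU (0 to 4), and for no other comparison. The widest of the others were mDM MSU (1263 to 2526), Bay in MSU (119 to 192) and Bay in PBS (95 to 162). A group of 2 then has 1 library, which is assumed to vary like the other groups. Of the named genes' results, 25795 kept their side of the threshold, 626 lost and 70 gained a call. The correlation of MSU and LPS responses was 0.389 in BMDM and 0.370 in mDM over the more expressed genes. With MSU, 75.2% of list genes called in mouse had the same sign in human (73.9% of all called). Most genes lay below 0 in human: 81.4% of called mouse falls did, against 76.5% of all genes. Of called mouse rises 62.3% lay above 0, against 23.5% of all genes. The alternatives planned for raw counts were not run, because the tables hold TPM. Recovered depth went down to 2.08 M reads, which limits what can be seen of genes with few reads.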

Other observations

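The tests of the MSU-risen genes in the other sets, the further comparisons of siRNA and genotype and the measures of the batches were chosen after results were seen, and the counts of splits were planned. In LPS-treated BMDM, silencing Jun lowered the protease inhibitor gene Serpina3g (-2.23), the endosomal receptor gene Tlr9 (-1.86), the cyclin gene Ccnd1 (-1.83) and the chemokine gene Cxcl9 (-1.72), and raised the activin gene Inhba (1.78) and the growth factor gene Csf3 (1.63), in limma with n = 3 and 3. Silencing Fosl1 in LPS raised the iron exporter gene Slc40a1 (1.71) and Cdk4 (1.28) and lowered Tm4sf19 (-1.67), Tlr9 (-1.34) and Serpina3f (-1.34), with n = 2 and 3. These genes were chosen after their values were seen. Fosl1 itself was under 1 TPM in LPS. Both comparisons use the same 3 siControl LPS libraries, so a gene that falls with both, such as Tlr9 or Serpina3f (-1.60 with siJun), may reflect those libraries. A difference between the siRNA files cannot be told apart from an effect of the siRNA there, since each came in a file of its own. By interaction with LPS, 7 genes passed for siJun and 6 for siFosl1. Without a stimulus, 42 genes differed between Myd88 knockout and wild type, with 776 in LPS and 61 in MSU.

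The genes that rose with MSU in the BMDM set were followed in the other sets, in libraries that took no part in choosing them. In the JNKi by MSU interaction their median was -0.35, against 0.08 over all genes, and 80.5% of the 763 genes lay below 0 (camera adjusted p = 1.71e-05 with an estimated correlation). In the Bay by MSU interaction the median was 0.34, against -0.05 over all genes (adjusted p = 9.14e-06). Without replicates 2 and 5 of vehicle PBS and MSU the medians were -0.42 and 0.28, and with partners averaged -0.34 and 0.34. With partner pairs as units, 1 of 200 splits, the real one, was as far from 0 for JNKi (permutation p = 0.005) and 20 for Bay (p = 0.1). Some of these splits turn the interaction into a sum of inhibitor effects, and both inhibitors had effects in PBS and MSU. The permutation p is therefore not exact for the interaction and does not decide it. That JNK carries a broad part of the crystal response is a hypothesis, which SP600125 at 20 µM alone cannot decide. For Bay chance is not excluded. The interactions share the vehicle libraries, which push both the same way, whereas the medians went opposite ways. With siJun in MSU the median was -0.16 against 0.05 (adjusted p = 0.0314), with siFosl1 -0.15 (0.101), and in the genotype by MSU interaction -0.10 against 0.07 (0.0751), each with an estimated correlation. Genes that fell with MSU moved the other way, at 0.30 with JNKi (0.00265) and -0.31 with Bay (1.38e-04).

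In the inhibitor set the 2 batches took 32.3% of the variance left after the groups, with 73 of 9038 genes over 0.5 log2 units apart and 2645 genes at an adjusted p under 0.05 for the batch.

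Other splits of the same libraries into groups of the same size were fitted, all 10 for groups of 3 and 100 drawn otherwise. For BMDM MSU (2033 genes, highest other split 0), BMDM LPS (5768, 0), BMDM MSU against LPS (4311, 0), siControl MSU (1632, 1), knockout MSU (1708, 1) and knockout LPS (4493, 1), only 1 split, the real one, gave as many, but 10 splits are too few for under 1 in 20. In the BMDM set, whose numbers pair the samples, the other splits called 0 genes whether or not they parted every pair. With libraries taken as exchangeable, chance was excluded, with 1 of 100 splits, for mDM MSU (1817, highest other 1344), mDM LPS (4215, 2029), mDM MSU against LPS (2913, 1367), vehicle MSU (1328, 506) and vehicle LPS (4937, 2798). It was also excluded for JNKi in MSU (371, 238), LPS (1348, 467) and PBS (364, 151), Bay in MSU (155, 60), LPS (818, 141) and PBS (122, 61), JNKi by LPS (1411, 728) and Bay by LPS (535, 461), each with 1 of 100. Partner libraries of the inhibitor set deviated together, and with partner pairs as units the groups hold at most 3, too few splits for under 1 in 20 in its comparisons of 2 groups. For the interactions, 100 of the 200 splits that keep partner pairs together were drawn after these results were seen. As many genes were called in 28 of 100 for JNKi by MSU (highest other 927), 16 for Bay by MSU (1362), 9 for Bay by LPS (1628) and 4 for JNKi by LPS (1685). For the last, 4 of 100 is under 1 in 20, but close to it and from a draw of 100 of the 200 splits. With partners as units, chance was therefore not excluded for JNKi by MSU, Bay by MSU and Bay by LPS. For JNKi by LPS the draw leaves it unsettled, and some of these splits turn the interaction into a sum of effects. For Bay by MSU (73 genes) 3 of 100 splits gave as many, the highest 155, which is under 1 in 20 only with libraries as units, and 40 genes passed without replicates 2 and 5 of vehicle PBS and MSU. For JNKi by MSU (134 genes) 11 of 100 did, the highest 378, so chance was not excluded for the count. Splits with libraries as units can also carry an inhibitor's own effects into an interaction, so they do not decide it. A split that calls several times the real count may come from such a sum of effects or from a structure of the samples, which was not tested. Comparisons with a group of fewer than 3 libraries were not split.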
